A study of Homo sapiens with 6 samples.

How the data were processed

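The files held droplet single-cell RNA counts from 6 libraries. Per the labels, tissue from the prostates of 3 donors was digested with collagenase I (5 mg per ml, 4 hours), viable cells were sorted, about 17400 cells were loaded per library, and the 3' kit of version 2 was used throughout. The labels name 2 sequencing set-ups, a NextSeq 500 with reads of 26 and 58 cycles and a NovaSeq 6000 with paired reads of 150, without saying which library had which. Read length could therefore not be set against the zones. Per the submitters' processing notes, reads were processed with Cell Ranger 4.0.0 on GRCh38, and per the labels the deposit re-analyses earlier libraries. The deposited values are whole-number UMI counts per gene and barcode, without normalization. The annotation they were counted on and how reads shared between genes were treated are not given in the sources used here.

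Barcodes were kept with at least 500 UMIs, at least 250 genes and at most 20% mitochondrial UMIs. Doublets were scored per library with Scrublet (scanpy 1.11.5). Its own threshold marked under 0.5% of each library, so the cells with the highest scores were removed, 6.05% to 7.28% per library. Cells were normalised to 10000 UMIs and log-transformed, and 3000 variable genes, 30 principal components and 15 neighbours were used. Leiden clustering (leidenalg 0.10.2, Python 3.11.15) was run at resolution 1.0 without batch integration. To name clusters, the log2 of CPM plus 10 of each marker was scaled from 0 in the lowest to 1 in the highest cluster and averaged over a class's markers, with at least 3 markers detected. The best class had to lead the next by 0.12, and a cluster with more of the fixed markers of another class than of its own among its top 10 genes stayed unnamed. Cluster 14 had 1 T cell marker there, IL7R, and 1 plasma cell marker, JCHAIN, beside immunoglobulin genes that were on no marker list, and is reported by number. This score and margin were chosen after the data were seen, as was naming by best score alone. Clusters 19, 27 and 28 stayed unnamed, with 0.262%, 0.597% and 0.115% of peripheral zone cells and 0.149%, 0.298% and 5.85% of transition zone cells. Genes of chromosome Y, XIST, immunoglobulin and T cell receptor segments, clone-based names and duplicate symbols were left out of the gene tests, which left 23299 genes and removed 0.526% of UMIs.

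Counts were summed per library and class. Libraries with at least 20 cells of the class entered a test, with at least 2 libraries per zone. The tests were edgeR 4.0.16 quasi-likelihood tests with robust fitting, TMM and filterByExpr in R 4.3.3, with Benjamini-Hochberg adjustment at 0.05. Fits without the donor were fixed as the reported ones before the data were examined, with the donor as a block as an alternative. Adjusted p-values of genes are from edgeR 4.0.16 and those of lists from camera (limma 3.58.1). Camera was run on log2 CPM (prior count 2, preset correlation 0.01, at least 5 members) over 28 lists fixed before the data were examined, beside camera with an estimated correlation and fry. Cell shares were tested with edgeR on cell numbers and with exact permutation tests. The other alternatives were DESeq2 1.42.0, other size factors, no filter on low counts, doublets kept, at most 10% mitochondrial UMIs, Leiden resolution 2.0, clustering without marker genes, and leaving out each library or donor. The pericyte test, the refit on 1 club cluster and all alternatives run together with the block were added after the data were seen.

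Per the labels the same donor gave a library of each zone, so the donors pair the libraries. The deviations of a donor's libraries from their zone means correlated at 0.826, 0.655 and 0.795 over all cells, across 6636 genes, which are not independent replicates. The lowest pair stood at 0.733 in basal cells, 0.570 in hillock cells and 0.149 in fibroblasts. Results with the block are therefore printed beside those without it; in luminal cells, for example, it called 183 genes. Luminal, club, endothelial, myeloid, pericyte and cluster 14 cells had 5 libraries and 2 donor pairs, which left 1 residual degree of freedom in the blocked fit. Its errors then rest mostly on the spread pooled across genes. In basal, hillock and fibroblast cells 2 were left, and the pooled spread outweighed them as well. It counted for a median of 7.899 degrees of freedom in basal and 9.395 in fibroblast cells. In hillock, endothelial and cluster 14 cells that median was infinite, so the errors of most genes there rest on the pooled spread alone. In club cells it was 1257, so the errors rest on that spread almost alone. Blocked p-values in these classes therefore measure little or nothing of a gene's own spread between donors. Standard errors of log2 differences are the absolute difference divided by the square root of the F statistic. No libraries agreed within sampling noise (chi-square per degree of freedom 85.9 to 477 over pairs).

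The genes named follow a rule fixed before the data were examined. Among genes called at 0.05, with the same sign in every donor with both libraries and at least 20 CPM in the higher zone, it takes the 12 largest in each direction. Where fewer than 5 pass it takes the 5 with the smallest p, and from each list at most 5 members by p. Applying it to the blocked fits was decided after the data were seen. Of the 98 genes named from blocked fits, 6 were called without the block and 98 had the same sign there. In the comparison of fibroblasts with epithelium SFRP4, ERBB3, MET, WNT7B, SRD5A2 and LGR4 fall outside the 5 smallest p of their list and were chosen after their values were seen. AKR1C1, AKR1C2, AKR1C3, GSTA1, RLN1, CCL3, CCL4, HSPA1A, HIST1H4C and RPS10 have near-identical relatives or pseudogenes, and DUOX2 overlaps DUOXA2, so their counts are uncertain as far as reads are shared. Some genes that the rule or the lists hold are not reported here.

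The fits were tested on simulated counts drawn from the real means and library sizes, with 200 genes changed. For each fit the counts were drawn with the spread that the same fit had estimated, so the fits did not see the same data. The shares below therefore do not compare the fits, and do not check whether the blocked spread was estimated well. In basal cells (13634 and 13676 genes) the fit without the block recovered 34% and the blocked fit 100% of genes changed by 2 on the log2 scale, and 1% and 98% of those changed by 1. In club cells (10312 and 10340 genes) it was 13% and 94%, and 0% and 26%. In luminal cells (11236 and 11476 genes) it was 5% and 100%, and 0% and 92%. Of the genes called by the blocked fit 20 of 212 were false in simulated luminal cells and 23 of 221 in simulated basal cells, more than the nominal share. UMIs per class and library in the class tests ran from 109700 (myeloid) to 32610000 (basal), so fold changes in small classes carry more counting error.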

Results

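Single-cell RNA libraries were prepared from the prostates of 3 organ donors. Each donor gave 1 library from the peripheral zone, the glandular part at the back and sides of the organ. Each also gave 1 library from the transition zone together with the urethra, here called the transition zone. A difference given for the transition zone can therefore not be assigned to that zone rather than the urethra. The measurement was the number of unique molecular identifiers (UMIs) per gene and cell, in 3 libraries of viable sorted cells per zone. The deposited matrices held 6602 to 9525 barcodes and 32157666 to 68534997 UMIs per library. After filtering, 41246 of 47725 barcodes were kept. The median was 3356 UMIs per cell in the shallowest library (transition zone, donor 2) and 6568.5 in the deepest (transition zone, donor 3). Clustering gave 29 clusters, of which 18 drew over 80% of their cells from 1 donor. From markers fixed beforehand, 24795 cells were basal-like, 3420 hillock-like (a KRT13-positive epithelium) and 2542 club-like (a secretory epithelium that resembles airway club cells). A further 2312 cells were luminal-like and 1568 fibroblast-like. Gene positions are on GRCh38 with GENCODE 29, and levels are in CPM, UMIs normalised to the total of the class in a library.

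The first question was whether the zones differed in which cells they held. Luminal cells, the secretory cells of the prostatic glands, made up 7.68% ± 6.31 of kept cells in the peripheral zone and 3.21% ± 3.40 in the transition zone (SD, n = 3 libraries each). Their share was lower in the transition zone in 3 of 3 donors. In donor 2 this was 43 cells against 1. The transition zone library of donor 2 was 81.1% basal and 15.7% unnamed, and also held few cells of other classes, such as 15 club, 2 endothelial and 0 myeloid cells. Hillock cells made up 4.97% ± 5.03 and 12.98% ± 10.2, and were higher in the transition zone in 2 of 3 donors. Among epithelial cells alone the luminal share was 9.71% ± 8.37 and 4.98% ± 5.997, and the hillock share 5.50% ± 5.35 and 17.7% ± 12.9. Neither share passed a test of the zone difference. edgeR called 0 of 12 classes among all kept cells and 0 of 4 among epithelial cells, 0 at an unadjusted p under 0.05, and 0 with the donor as a block. The hillock class depended on the clustering. It held 1012 peripheral zone cells, but 446 with doublets kept, 286 with at most 10% mitochondrial UMIs and 395 with marker genes left out of the clustering. Of the 1012 cells 714, 723 and 663 were unnamed there. The log2 difference of the hillock share was 1.38, and 2.58, 2.70 and 2.52 in these settings, none of them called. Luminal cells of the peripheral zone went from 1725 to 2719 with doublets kept and 2315 with at most 10% mitochondrial UMIs. Over all kept cells the exact permutation p was 0.3 for luminal and for hillock cells (two-sided; the smallest possible is 0.1). Among epithelial cells the exact permutation p was 0.5 for luminal and 0.3 for hillock cells. The sort for viable cells and the digestion can set such shares. Unnamed cluster 28, led by CCL20, FST, FABP5 and AREG, held 5.85% of transition zone and 0.115% of peripheral zone cells, nearly all from the transition zone library of donor 2.

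**Figure D1:**
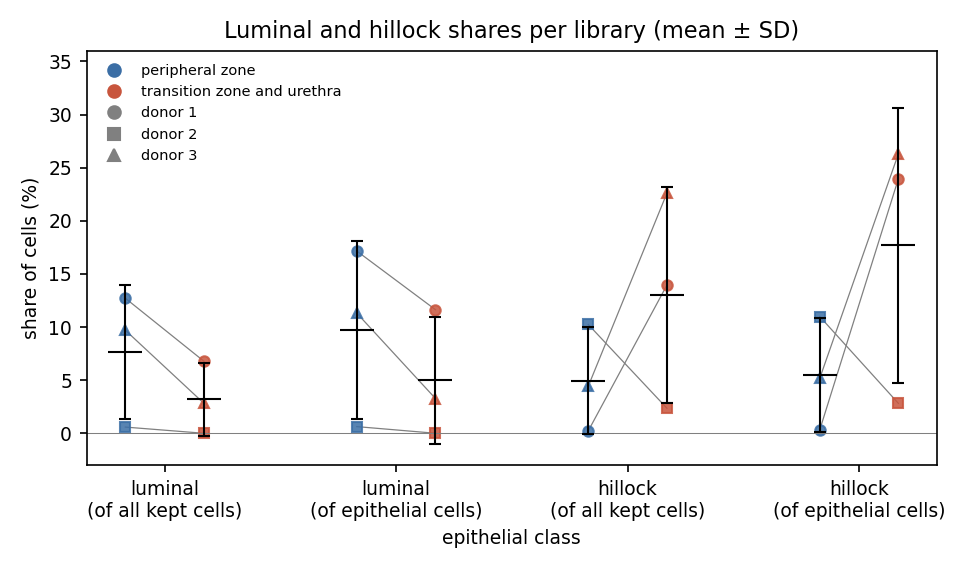
Share of luminal and hillock cells in each library (y axis, percent), of all kept cells and of epithelial cells, in the peripheral zone (blue) and the transition zone with the urethra (red). Symbols stand for donors, grey lines join the libraries of 1 donor, and black bars give the mean ± SD of 3 libraries; the luminal share was lower in the transition zone in 3 of 3 donors, and the hillock share higher in 2 of 3.

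The next comparisons asked which genes differed between the zones within a cell class. In club cells, genes of mucosal defence were among those higher in the libraries of transition zone and urethra. LCN2 (ENSG00000148346, chromosome 9, 128149071 to 128153455), a lipocalin that binds bacterial siderophores, stood at 13570 ± 4717 CPM (SD, n = 2 libraries) against 494 ± 289 in the peripheral zone (n = 3). The log2 difference was 5.02 ± 0.59 (SE; edgeR adjusted p = 0.0256). LCN2 was also higher in each of the 7 classes it was tested in, all 7 at an unadjusted p under 0.05 with the donor as a block. LYZ, the antibacterial enzyme lysozyme, stood at 145 ± 12.8 against 2.89 ± 2.75 CPM (5.63 ± 0.82, adjusted p = 0.0480). PSCA, a glycoprotein of the cell surface (chromosome 8, 142670308 to 142682724), stood at 1956 ± 301 against 148 ± 64.5 CPM (3.97 ± 0.51, adjusted p = 0.0256). AKR1C3 (ENSG00000196139, chromosome 10, 5035354 to 5107686), a reductase that makes testosterone from androstenedione, had 263 UMIs in the transition zone and 2 in the peripheral zone (26.6 ± 11.1 and 0.0946 ± 0.164 CPM). CRISP3, AGR3, the uroplakin UPK1A, the interferon-induced IFI27, the tryptophan-degrading enzyme KYNU and the galectin LGALS4 were also higher, by log2 differences of 3.46 (UPK1A) to 6.46 (CRISP3). In all, 13 of 10827 genes were called, all 13 higher in the transition zone.

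With the donor as a block, 526 genes were called in club cells, 345 higher and 181 lower in the transition zone, from the 2 donors with club cells in both zones. HPGD, which degrades prostaglandins, was higher by 5.62 ± 0.41 (log2, SE; adjusted p = 3.52e-35), the mucus protein FCGBP by 5.68 ± 0.44 and the secreted BPIFB1 by 5.29 ± 0.43. DUOX2, an oxidase that makes hydrogen peroxide, was higher by 5.28 ± 0.48 and its maturation factor DUOXA2 by 6.05 ± 0.48. Genes of the glandular prostate were among those lower. The prostate-specific antigen KLK3 fell by 1.66 ± 0.31 on the log2 scale and the prostatic transglutaminase TGM4 fell by 2.54 ± 0.38. The secretoglobin SCGB1D2 fell by 4.42 ± 0.55 and PRR4 fell by 3.33 ± 0.38. KRT14, a keratin of basal cells, fell by 2.80 ± 0.34. SIM2, a transcription factor, had 207 UMIs in the peripheral zone and 1 in the transition zone, and WIF1, an inhibitor of WNT signalling, 149 and 2.

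By the lists fixed beforehand, 18 of 19 airway-type secretory and antimicrobial genes were higher in transition zone club cells (median log2 difference 2.39; camera adjusted p = 8.36e-15). Over all genes 2 were called, adjusted over the list alone 16, and with the block 16 rose and 1, the defensin DEFB1, fell, which was lower in all 7 classes it was tested in. Of the list's 21 genes, 7 were also club markers. All 8 MHC class II genes tested, which present antigen to helper T cells, were higher (median 3.25, adjusted p = 2.65e-12; 8 called when adjusted over the list alone, 8 with the block). HLA-DRA stood at 437 ± 188 against 20.4 ± 28.2 CPM and the invariant chain CD74 at 1206 ± 305 against 141 ± 64.7. Of 13 urothelium genes 11 were higher (median 0.99, adjusted p = 7.58e-09; 6 adjusted over the list alone, 7 with the block, among them UPK1A and VSIG2). These genes cannot be assigned to the transition zone rather than the urethra. Of 16 steroid receptors and enzymes 12 were higher (median 0.61, adjusted p = 1.70e-05; 6 adjusted over the list alone, 7 with the block, among them AKR1C2 and AKR1C3). Of 10 genes of prostatic fluid 9 were lower (median -0.65, adjusted p = 0.0128; 1 adjusted over the list alone, 5 with the block). With an estimated correlation each of these 5 lists had adjusted p = 0.82.

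The zones drew their club cells from different clusters. All 1616 peripheral zone cells lay in cluster 4. Of the transition zone cells 597 lay in cluster 11, nearly all from donor 1, and 329 in cluster 4. LCN2, PSCA, HPGD, FCGBP and BPIFB1 were also among the 10 genes that set cluster 11 apart, and PRR4 among those of cluster 4. SIM2 was among those of basal cluster 0, and KRT14 and WIF1 among those of basal cluster 26. Within cluster 4 alone edgeR called 0 genes (135 at an unadjusted p under 0.05), and 13 with the block. The count of 13 went to 0 without the peripheral zone library of donor 2 or both its libraries, and to 1 without the peripheral zone library of donor 3. It was 29 without the peripheral zone library of donor 1, 104 without the transition zone library of donor 3, and 72 and 93 without both libraries of donors 1 and 3. Each fit without a library of donor 1 or 3 from the transition zone held 1 transition zone library, assumed to vary like those of the peripheral zone. It was 53 at a finer clustering, 22 with marker genes left out of the clustering, 236 without a filter on low counts and 73 with DESeq2. Of the 10 genes named from the fit without the block, all 10 lost their calls without the peripheral zone library of donor 2 or 3 or both libraries of donor 2. CRISP3, LYZ, UPK1A, IFI27, KYNU and LGALS4 lost theirs without the transition zone library of donor 1, UPK1A and KYNU without donor 1, UPK1A without the peripheral zone library of donor 1, LYZ without donor 3, and LYZ and UPK1A with marker genes left out of the clustering. With these left out the blocked count was 330, and TGM4 and WIF1 lost their calls. With doublets kept or at most 10% mitochondrial UMIs, at most 5 peripheral zone cells were named club, and no test could be made. Of the 1616 peripheral zone club cells 724 and 719 were then named luminal, while 646 were unnamed with doublets kept and 671 were named neuroendocrine with at most 10% mitochondrial UMIs. At the finer clustering 317 of them were named neuroendocrine, as were 92 of the 329 transition zone cells of cluster 4. Named basal were 241 of the 1616 with doublets kept and 369 with marker genes left out of the clustering. Of the 329 transition zone cells 75 and 89 were.

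**Figure D2:**
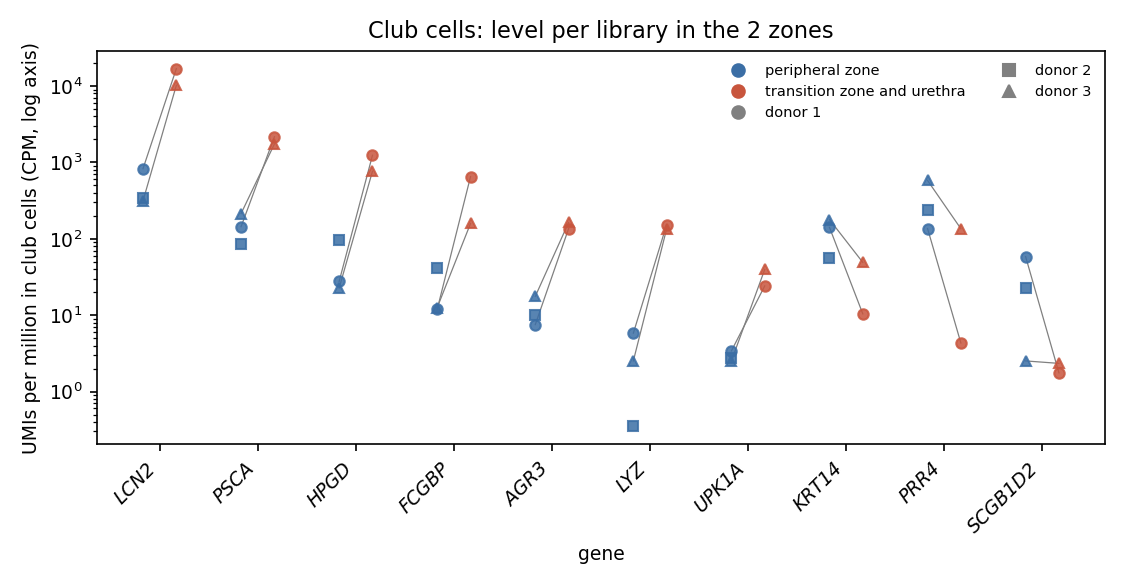
Level of 10 genes in club cells of each library (y axis, CPM, logarithmic), in the peripheral zone (blue, 3 libraries) and the transition zone with the urethra (red, 2 libraries with at least 20 club cells). Symbols stand for donors and grey lines join the libraries of 1 donor; LCN2 lay at 13570 CPM on average in the transition zone and 494 in the peripheral zone.

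Hillock cells differed between the libraries of peripheral zone and of transition zone with urethra when each donor was compared with itself. FABP4, a fatty acid binding protein (ENSG00000170323, chromosome 8, 81478419 to 81483263), had 1490 UMIs in the transition zone and 2 in the peripheral zone (43.0 ± 23.6 and 0.1197 ± 0.207 CPM; SD, n = 3 each). The trypsin inhibitor SPINK1 was higher in the transition zone by 3.51 ± 0.27 (log2, SE; blocked adjusted p = 4.72e-35). Its level varied widely between libraries, at 197 ± 255 CPM in the transition zone and 20.7 ± 28.0 in the peripheral zone (SD). The steroid reductases AKR1C3 and AKR1C1 were higher by 3.76 ± 0.36 and 2.71 ± 0.24, and the uroplakin UPK1B by 3.33 ± 0.40. PIGR, which carries immunoglobulin A across epithelium, was higher by 4.08 ± 0.66. SPINK1 and PIGR were also among the leading genes of club cluster 11, nearly all from the transition zone library of donor 1. The ammonium transporter RHCG fell by 1.46 ± 0.21, the calmodulin-like CALML3 fell by 1.58 ± 0.27, CLIC3 fell by 1.74 ± 0.32 and HOPX fell by 1.31 ± 0.27. All 8 MHC class II genes tested were higher (median 1.998, adjusted p = 1.88e-04; 4 adjusted over the list alone, 4 with the block). CD74, for example, stood at 279 ± 197 against 79.9 ± 43.8 CPM. Of 9 prostatic fluid genes 8 were lower (median -0.56, adjusted p = 0.0390; 0 adjusted over the list alone, 3 with the block). With an estimated correlation both lists had adjusted p = 0.82.

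In all, 232 genes were called in hillock cells with the block, 158 higher and 74 lower, and 0 of 10614 without it (edgeR; 210 at an unadjusted p under 0.05; DESeq2 called 9). Without the block the count was 5 with no filter on low counts, 2 with marker genes left out of the clustering, 1 with doublets kept, and 1 without the transition zone library of donor 2 or both its libraries. Different clusters held the class in different donors, and 1 cluster held most of a donor's hillock cells in both zones. Cluster 6, mostly from donor 2 and led by RHCG among others, held 717 of the peripheral zone cells. From donor 2 it held 709 peripheral and 142 transition zone cells. Cluster 21, mostly from donor 3, held 1405 of the transition zone cells, and 252 peripheral and 1380 transition zone cells of donor 3. Cluster 17, from donor 1, held 852 of the transition zone cells, and 14 peripheral and 844 transition zone cells of donor 1. AKR1C1 was among its leading genes. Donor 1 had 21 hillock cells in the peripheral zone and 850 in the transition zone. The blocked count was 128, 109 and 92 without donors 1, 2 and 3, 66 with at most 10% mitochondrial UMIs and 47 with doublets kept. AKR1C3 and HOPX lost their calls without donor 1, CLIC3 without donor 2, and RHCG, CALML3, CLIC3 and HOPX without donor 3. With doublets kept UPK1B, PIGR, CALML3, CLIC3, HOPX and CD74 lost theirs, and with at most 10% mitochondrial UMIs AKR1C3, UPK1B, CALML3 and CD74. PIGR and RHCG lost theirs with marker genes left out of the clustering.

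In luminal cells the glutathione transferase GSTA1 was higher in the transition zone by 2.25 ± 0.20 (blocked log2 difference, SE; adjusted p = 5.33e-04). The phospholipase PLCG2 was higher by 1.96 ± 0.22, the fatty acid hydroxylase CYP4F22 by 1.90 ± 0.21, and KRT13, a hillock marker, by 1.97 ± 0.24. GBP2 (ENSG00000162645, chromosome 1, 89106132 to 89150456), an interferon-induced GTPase, was higher by 1.46 ± 0.17 and TNFAIP2 by 1.66 ± 0.20. So were the chemokines CXCL10 by 1.95 ± 0.26, CXCL1 by 0.88 ± 0.13 and CXCL8 by 0.79 ± 0.11. Without the block their differences were 0.97 ± 0.97, 1.25 ± 1.07 and 0.46 ± 0.77. CXCL10 stood at 32.9 ± 25.9 CPM in the transition zone and 28.8 ± 34.9 in the peripheral zone (SD). The hormone relaxin RLN1 was lower, at 12.2 ± 5.07 CPM (n = 2) against 25.4 ± 18.5 (n = 3), and the receptor TNFRSF19 fell by 1.25 ± 0.20. Of 17 NF-kB and inflammatory cytokine genes 15 were higher with the block (median 0.45, adjusted p = 0.0030; 6 rose and 0 fell, and 9 were called when adjusted over the list alone). That list had adjusted p = 0.0778 without the block. Squamous and stratified epithelium genes were higher in 7 of 10 cases with the block (median 0.52, adjusted p = 0.0104, 0.1312 without it), and 4 rose, KRT13, SERPINB1, SERPINB3 and PSCA (4 adjusted over the list alone). Of that list's 20 genes 9 were markers of other classes. KRT13 stood at 26.0 ± 12.9 CPM in luminal cells of the transition zone and 8.10 ± 3.67 in the peripheral zone. Its rise was not particular to luminal cells. With the block KRT13 and SERPINB1 were also called higher in endothelial cells, by 1.84 and 0.55. With the block and an estimated correlation both lists had adjusted p = 0.79.

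MSMB (ENSG00000263639, chromosome 10, 46033307 to 46046269), a major protein of prostatic fluid, stood at 34410 ± 18060 CPM in luminal cells of the peripheral zone and 24200 ± 12820 in the transition zone, and fell by 0.72 ± 0.08 on the log2 scale with the block. MSMB was lower in all 9 classes it was tested in, in 7 at an unadjusted p under 0.05 with the block. Of 14 prostatic fluid genes 9 were lower (median -0.21, adjusted p = 0.64). The 22 androgen-regulated genes had a median of 0.07, while camera's direction was down (adjusted p = 0.94). With the block 17 of the 22 were lower and the median was -0.13 (adjusted p = 0.2333). MHC class II genes were higher in 7 of 7 cases (median 0.48, adjusted p = 0.0022; 0 adjusted over the list alone), as were 10 of 16 airway-type genes (median 0.66, adjusted p = 0.0143; 0 adjusted over the list alone, 2 up and 1 down with the block). All 24 genes of the fixed ribosomal protein list were higher (median 0.37, adjusted p = 5.02e-04, 0.0189 with the block; 0 adjusted over the list alone). With an estimated correlation these 3 lists had adjusted p = 0.82. Other ribosomal protein genes went the other way. With the block RPS10, which is not on that list, and RPS29 were lower in all 9 classes they were tested in. The block called 183 of 11737 genes from 2 donors, 108 higher and 75 lower. Without it edgeR called 0 (63 at an unadjusted p under 0.05; DESeq2 called 0), 9 without donor 1, and 1 without donor 3 or its transition zone library, each with 1 transition zone library assumed to vary like the others. The blocked count was 41 with marker genes left out of the clustering, 110 at a finer clustering, 81 with doublets kept and 80 with at most 10% mitochondrial UMIs. KRT13 and CXCL10 lost their calls in the last 2 settings and GSTA1 in the last.

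Whether the zone effect differed between luminal and basal cells was tested itself. edgeR called 0 of 14324 genes (118 at an unadjusted p under 0.05; DESeq2 called 1, as did edgeR with no filter on low counts). The count was 8 and 6 without the transition zone libraries of donors 1 and 3, 3 and 1 without their peripheral zone libraries, and 6 and 2 without both. Fits without either of these transition zone libraries held 1 library of that zone, assumed to vary like the others. Libraries were the blocks, and the pairing of donors was not used. In simulated counts the full fit recovered 15% of genes changed by 2 on the log2 scale and 1% of those changed by 1. Of its 27 calls there, 11 were false. A count of 0 therefore does not show that the zone effect was alike in luminal and basal cells.

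In basal cells of the transition zone, the chemokine CCL20 (ENSG00000115009, chromosome 2, 227805739 to 227817564) stood at 299 ± 114 CPM against 148 ± 59.3 in the peripheral zone (SD, n = 3 each; blocked log2 difference 1.02 ± 0.13, SE; adjusted p = 0.0112). The prostaglandin synthase PTGS2 was higher by 1.01 ± 0.15, the interleukin-1 receptor antagonist IL1RN by 0.99 ± 0.14, the interleukin-33 receptor IL1RL1 by 1.15 ± 0.15 and the RNA-binding IGF2BP2 by 1.43 ± 0.22. PCLAF, a partner of the replication clamp, fell by 1.91 ± 0.22 and UBE2C, a ubiquitin-conjugating enzyme of mitosis, fell by 2.48 ± 0.32. The histone gene HIST1H4C fell by 0.94 ± 0.13 and the tetraspanin TSPAN8 fell by 1.35 ± 0.16. All 14 cell cycle genes tested were lower (median -1.53, adjusted p = 7.38e-09; 0 adjusted over the list alone, 1 with the block and 14 with the block when adjusted over the list alone). Of the list's 15 genes, 10 were the markers of cycling cells. Cycling cluster 3, kept apart from basal cells, held 36 peripheral and 12 transition zone cells, all 48 of donor 1, while the one at a finer clustering held 172 cells, among them 70 and 47 of donor 3. Of 23 NF-kB and cytokine genes 18 were higher (median 0.24, adjusted p = 0.0121; 0 adjusted over the list alone, 1 with the block). With an estimated correlation the cell cycle and NF-kB lists had adjusted p = 0.82.

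Prostatic fluid genes were lower in basal cells of the transition zone in 11 of 12 cases (median -1.44, adjusted p = 4.44e-07, and adjusted p = 0.82 with an estimated correlation; 0 adjusted over the list alone, 2 with the block). MSMB stood at 26.9 ± 20.9 CPM in the transition zone and 218 ± 214 in the peripheral zone, and KLK2 at 3.49 ± 3.04 and 14.4 ± 10.8. Over classes other than luminal, 12 luminal secretory genes stood at a median of 5.45% of their level over all cells of the library, with club cells at 28.0% to 261.4% and the pericyte-like cells of the transition zone of donor 3 at 99.02%. Immediate early genes were lower in 18 of 22 cases (median -0.27, adjusted p = 0.0299, and adjusted p = 0.82 with an estimated correlation; 0 adjusted over the list alone). Heat shock genes were lower in 13 of 15 cases (median -0.24, adjusted p = 0.4194). With the block all 15 were lower (median -0.26, adjusted p = 8.58e-04, and adjusted p = 0.79 with an estimated correlation), and 1, DNAJB1, fell (4 adjusted over the list alone). DNAJB1 was lower in all 9 classes it was tested in. Most basal cells of the peripheral zone lay in clusters 2 (3984), 26 (2113) and 0 (1853), and the largest clusters in the transition zone were 23 (2275), 8 (1781) and 5 (1753). Each of these clusters drew mostly on 1 donor, in both zones. Cluster 2, for example, held 3978 peripheral and 1300 transition zone cells of donor 1, and cluster 23 held 1692 and 2261 of donor 2. Clusters 1, 7 and 23 were led by heat shock or immediate early genes, and basal cluster 25 had 14.8% mitochondrial UMIs. With the block 90 genes were called, 27 higher and 63 lower, and 0 of 13892 without it (edgeR; 159 at an unadjusted p under 0.05; DESeq2 called 11). The blocked count was 34, 497 and 72 without donors 1, 2 and 3, 54 with at most 10% mitochondrial UMIs, 204 with doublets kept, 201 at a finer clustering and 244 with every cluster given its best-scoring name. PTGS2, IL1RN, IL1RL1, PCLAF and HIST1H4C lost their calls without donor 1, and IL1RN, HIST1H4C and UBE2C without donor 3. PCLAF lost its call in all 4 of the other settings. IL1RN, IL1RL1 and HIST1H4C lost theirs with at most 10% mitochondrial UMIs, IL1RL1 with doublets kept, PTGS2, IGF2BP2 and UBE2C at the finer clustering, PTGS2 by best-scoring names and UBE2C with marker genes left out of the clustering.

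In fibroblasts CA3, a carbonic anhydrase (ENSG00000164879, chromosome 8, 85373436 to 85449040), stood at 132 ± 93.5 CPM in the transition zone and 2.07 ± 1.82 in the peripheral zone (SD, n = 3 each; blocked log2 difference 4.17 ± 0.56, SE; adjusted p = 0.0121). CA3 rested on 9 UMIs in the peripheral zone and 239 in the transition zone. The protease inhibitor TFPI2 was higher by 2.16 ± 0.28, the WNT antagonist DKK1 by 1.86 ± 0.33 and the growth factor NRG1 by 1.96 ± 0.36. The activity-induced ARC was higher by 2.60 ± 0.45 and the ubiquitin-like ISG15 by 1.60 ± 0.31. Osteomodulin OMD fell by 2.17 ± 0.30, tenascin TNC fell by 2.29 ± 0.41 and TAGLN, an actin-binding protein, fell by 1.44 ± 0.23. The WNT modulator SFRP4 fell by 1.68 ± 0.31, and the growth factor IGF1 fell by 1.45 ± 0.25, from 396 ± 120 to 141 ± 42.4 CPM. MSMB, a gene of luminal cells, fell by 2.36 ± 0.41. Of 11 steroid receptors and enzymes 9 were lower (median -0.56, adjusted p = 0.0194). So were 20 of 32 extracellular matrix genes (median -0.25, adjusted p = 0.0485; 0.0871 with the block). Of 22 immediate early genes, which also mark the response to dissociation, 18 were lower (median -0.43, adjusted p = 0.0266). With an estimated correlation each list had adjusted p = 0.82, and adjusted over each list alone 0 genes were called.

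Most fibroblasts came from donor 1. The peripheral zone libraries of donors 1, 2 and 3 held 528, 42 and 52 of them, and the transition zone libraries 803, 30 and 113. The block called 30 genes in fibroblasts, 17 higher and 13 lower. Without it edgeR called 0 of 4849 (105 at an unadjusted p under 0.05; DESeq2 called 2), 21 with no filter on low counts, and 1 without donor 1 or its transition zone library. The blocked count was 35, 197 and 57 without donors 1, 2 and 3. SFRP4, TAGLN and ISG15 lost their calls without donor 1, and NRG1, IGF1, ISG15 and MSMB without donor 3. DKK1, NRG1, ARC, ISG15, TNC and MSMB lost theirs with doublets kept. Smooth muscle cells were not tested, alone or against fibroblasts, as only 1 library per zone held at least 20 of them.

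Fibroblasts were then compared with epithelium to ask which hormone and signalling genes the stroma carried. Counts were summed per donor over both zones, and most fibroblasts came from donor 1. FGF7, the keratinocyte growth factor (ENSG00000140285, chromosome 15, 49423096 to 49488775), stood at 382 ± 164 CPM in fibroblasts (SD, n = 3 donors) and 0.972 to 1.91 in luminal, basal, club and hillock cells. The log2 difference was 8.08 ± 0.19 (SE; adjusted p = 6.25e-15). FGF2 was higher by 6.65 ± 0.32. IGF1 stood at 224 ± 44.5 CPM, HGF, the ligand of MET, at 54.1 ± 37.6 and FGF10 at 13.9 ± 4.22, each at or under 0.830 CPM on average in every epithelial class. The receptor ERBB3 fell by 4.75 ± 0.38 from epithelium to fibroblasts. MET fell by 3.07 ± 0.38, and stood at 4.91 ± 3.20 CPM in fibroblasts, 5.42 ± 4.50 in luminal and 84.6 ± 64.8 in basal cells. Of 25 growth factors and receptors 12 were higher and 10 lower (24 called when adjusted over the lists alone).

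Of 43 WNT, BMP, hedgehog and retinoid genes 32 were higher in fibroblasts and 3 lower (38 adjusted over the lists alone). RSPO3, which amplifies WNT signals, stood at 86.1 ± 97.4 CPM, WNT2 at 39.2 ± 27.5 and BMP5 at 18.3 ± 7.68, each at or under 0.148 CPM on average in every epithelial class. SFRP4 was higher by 8.01 ± 0.48 and DKK3 by 4.66 ± 0.28. WNT7B fell by 3.43 ± 0.58 and LGR4, a receptor for R-spondins, fell by 1.98 ± 0.49 from epithelium to fibroblasts. Among 20 steroid receptors and enzymes 11 were higher and 2 lower (14 adjusted over the lists alone). The progesterone receptor PGR was higher by 6.21 ± 0.52, the oestrogen receptor ESR1 by 4.79 ± 0.51 and SRD5A2, the reductase that makes dihydrotestosterone, by 3.76 ± 0.74. AKR1C1 was higher by 4.74 ± 0.33 than the epithelial mean, with 584 ± 613 CPM in fibroblasts and 419 ± 581 in hillock cells. SULT2B1, a sulfotransferase for cholesterol, fell by 5.26 ± 0.66. In all, 70 of 88 genes were called, 55 higher and 15 lower (76 adjusted over the lists alone), with cell type markers left out.

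**Figure D3:**
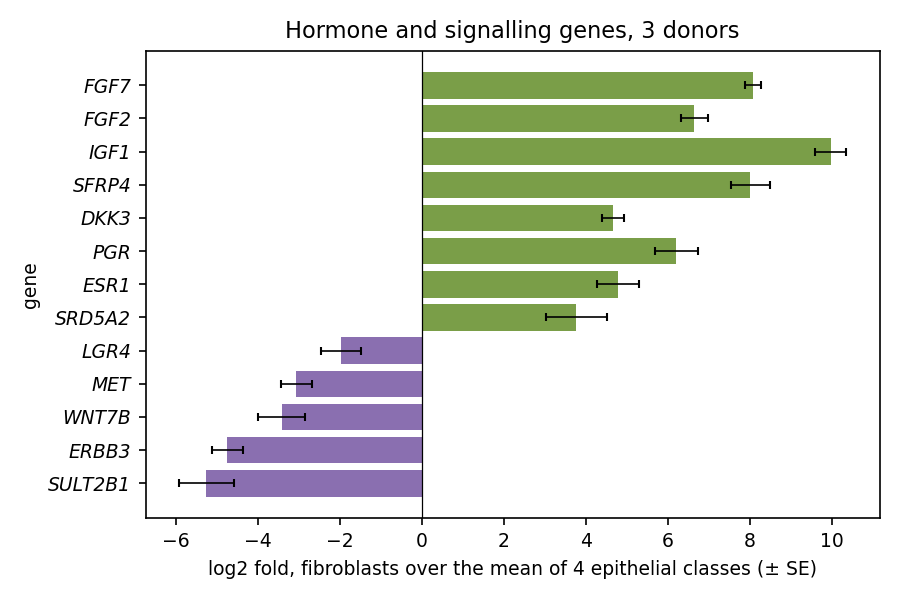
Log2 difference between fibroblasts and the mean of luminal, basal, club and hillock cells (x axis) for 13 genes, with bars for the standard error of the edgeR fit over 3 donors. Green bars are higher and purple bars lower in fibroblasts, from 9.97 for IGF1 to -5.26 for SULT2B1.

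In endothelial cells the collagenase MMP1 (ENSG00000196611, chromosome 11, 102789920 to 102798160) was higher in the transition zone by 3.18 ± 0.22 (blocked log2 difference, SE; adjusted p = 5.07e-45) and the stromelysin MMP10 by 2.62 ± 0.24. CXCL10 was higher by 3.00 ± 0.39, the heparan sulfate enzyme HS3ST2 by 3.18 ± 0.43, the nuclease DNASE1L3 by 2.54 ± 0.28 and the matrix protein EDIL3 by 2.80 ± 0.42. CYP26B1, which degrades retinoic acid, fell by 3.10 ± 0.39 and fibronectin FN1 fell by 1.95 ± 0.25. Of 20 genes of endothelial zonation 16 were lower with the block (median -0.37, adjusted p = 0.0026, 0.1312 without it). Among these 7 fell, such as SEMA3G and CA4, and 1 rose (10 adjusted over the list alone). GJA4, 1 of these 7, was among the leading genes of pericyte-like cluster 13. Genes of the contractile apparatus, found in mural cells, were lower in 10 of 10 cases with the block (median -0.47, adjusted p = 0.0012, 0.0725 without it), and TAGLN and TPM2 fell (2 adjusted over the list alone). Of 25 interferon genes 19 were higher with the block (median 0.29, adjusted p = 0.0012, 0.0575 without it; 3 rose and 1 fell, 9 adjusted over the list alone). With the block and an estimated correlation these 3 lists had adjusted p = 0.79. Heat shock genes were lower in 12 of 15 cases (median -0.24, adjusted p = 0.0355, and adjusted p = 0.82 with an estimated correlation; 0 adjusted over the list alone). With the block 6 fell, such as DNAJB1 by 1.54 ± 0.19 and HSPA1A, which fell by 1.31 ± 0.23. Without the block their log2 differences were smaller, at -0.93 ± 0.87 and -0.48 ± 1.07. All 24 genes of the ribosomal protein list, which does not hold RPS10, were higher (median 0.21, adjusted p = 0.01998, 0.0028 with the block, and adjusted p = 0.82 with an estimated correlation; 0 adjusted over the list alone).

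Prostatic fluid genes were lower in endothelial cells in 6 of 7 cases (median -1.28, adjusted p = 0.0029, and adjusted p = 0.82 with an estimated correlation; 1 adjusted over the list alone, 5 with the block). MSMB stood at 42.0 ± 5.46 CPM (n = 2) in the transition zone and 253 ± 259 (n = 3) in the peripheral zone. The block called 331 genes, 119 higher and 212 lower, from 2 donors, and the errors of most genes here rest on the pooled spread alone. MMP1 differed by 3.895 ± 1.307 (log2, SE) without the block. Without it edgeR called 0 of 8149 (51 at an unadjusted p under 0.05; DESeq2 called 0) and 16 with no filter on low counts. The count was 4 and 1 without the transition zone libraries of donors 3 and 1, and 7 and 2 without both libraries of these donors, each with 1 transition zone library assumed to vary like those of the peripheral zone. The blocked count was 67 with at most 10% mitochondrial UMIs, 116 with doublets kept and 145 with marker genes left out of the clustering. DNASE1L3 and HSPA1A lost their calls in each of these, CA4 in the first 2, SEMA3G and MSMB with doublets kept, and DNASE1L3 also without donor 2.

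Cluster 14 carried T and natural killer cell markers, was led by immunoglobulin genes of plasma cells, and had a median UMI count of 0.232 of that of its libraries. In it the chemokine CCL3 was higher in the transition zone by 1.03 ± 0.26 (blocked log2 difference, SE). Interferon gamma IFNG fell by 0.83 ± 0.23, TXNIP fell by 0.76 ± 0.20 and CCL20 fell by 1.23 ± 0.24. All 15 heat shock genes were lower (median -0.67, adjusted p = 0.0143, 0.1749 with the block, and adjusted p = 0.82 with an estimated correlation; 0 adjusted over the list alone). All 24 genes of the ribosomal protein list were higher there (median 0.23, adjusted p = 0.0079, 0.2347 with the block, and adjusted p = 0.82 with an estimated correlation; 0 adjusted over the list alone). The block called 23 of 2298 genes, 5 higher and 18 lower, and edgeR without it 0 (25 at an unadjusted p under 0.05; DESeq2 called 0). In myeloid cells the monocyte attractant CCL2 fell by 3.03 ± 0.41, CCL4 fell by 1.41 ± 0.22 and MSMB fell by 3.37 ± 0.40. The block called 11 of 2686 genes there, 2 higher and 9 lower, and edgeR without it 0 (20 at an unadjusted p under 0.05; DESeq2 called 0) and 3 with no filter on low counts. Without the transition zone library of donor 3 the unblocked counts were 12 in cluster 14 and 10 in myeloid cells, and without donor 3 they were 7 and 4, each with 1 transition zone library assumed to vary like those of the peripheral zone. With doublets kept the counts in cluster 14 were 1 without the block and 9 with it. There CCL3, IFNG, TXNIP and CCL20 lost their calls, as did CCL2 and CCL4 in myeloid cells, and CCL3 and IFNG also at a finer clustering. The blocked myeloid count was 34 without donor 2 and 17 to 28 with other filters or clusterings. Of the 23 and 11 calls, 11 and 8 were genes that shifted the same way in every class tested. RPS10, a ribosomal protein gene outside the list above, was 1 of them and fell by 1.80 ± 0.14 in cluster 14.

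Summed over all cells of a library, edgeR called 0 of 15878 genes with or without the block (322 without and 1816 with it at an unadjusted p under 0.05). DESeq2 called 41, and the blocked count was 435 without donor 2. Squamous and stratified epithelium genes were higher in endothelial (5 of 6; median 0.69, adjusted p = 0.0299) and myeloid cells (4 of 5; median 0.75, adjusted p = 6.59e-04). In both, 1 was called when adjusted over the list alone, and adjusted p = 0.82 with an estimated correlation. With the block the list of zinc and citrate handling was lower in club, hillock, endothelial and myeloid cells (medians -0.69, -0.37, -0.72 and -1.19; adjusted p = 0.0024, 0.0012, 1.55e-04 and 7.54e-05, and each adjusted p = 0.79 with an estimated correlation). Adjusted over the list alone 7, 6, 5 and 5 were called, and without the block the list passed in hillock cells alone among these 4 (adjusted p = 0.0299). Its members that fell were metallothioneins such as MT1E and MT1G, which bind metals, and SLC30A4 in club cells. With the block MT1E, MT1G and MT2A were lower in all 9 classes they were tested in, so these 4 results are not separate findings for each class. MT1E and MT1G were also among the leading genes of luminal cluster 9. Over all classes, 33 of 174 tests of a gene list passed, 18 higher and 15 lower in the transition zone, 50 with the block, and 0 with an estimated correlation or by fry.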

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

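The free RNA, transcript length and secretory gene tests and all counts over other splits were chosen after the results were seen. So was the definition of the set of genes that shift alike. The shared-read and club cluster tests were set before their results.

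Some genes went opposite ways between the zones in different cell classes, each called with donors as blocks in both classes, with 2 or 3 donor pairs. The differences themselves were not tested. IFI27 was higher in club (4.51) and lower in pericyte-like cells (-1.45) of the transition zone, a gap of 5.96 on the log2 scale. CXCL1 was higher in luminal and lower in pericyte-like cells, a gap of 2.05. CCL20 was higher in basal cells and lower in cluster 14 (gap 2.25). Taken as cluster 14 minus the other class, its gap was -2.69 against club and -2.45 against hillock cells, where it was higher. PTGS2 was higher in basal and lower in club (2.45) and endothelial cells (2.01). ARC was higher in fibroblasts and lower in endothelial cells (3.67). TAGLN was lower in fibroblasts and higher in hillock cells (-2.72). CCL2 was lower in myeloid and higher in pericyte-like cells (-3.69).

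A set of 51 of 6594 genes shifted the same way between the zones in every class tested, with an unadjusted p under 0.05 with the block in at least 5 of the 6 or more classes tested, 37 lower and 14 higher in the transition zone. Among them were RPS10, RPS29, SNHG25 and NMT1, all lower. MTRNR2L8, MTRNR2L10 and MTRNR2L12 were higher, at an unadjusted p under 0.05 with the block in all 9 classes. The set also held LCN2, MSMB, DEFB1, DNAJB1, MT1E, MT1G and MT2A, which are given above for single classes or lists. Free RNA as the whole cause is argued against: the shift would need a median of 32.18% of free RNA (quartiles 23.58 to 50.81), while luminal secretory genes showed 5.25% (4.211 to 6.941) with club cells left out, and an upper quartile of 9.534 with them. That bound was added after the median was seen, the first bound of 50 was not met, and 3 genes stay open, LCN2 (needing 3.32%), S100P (4.571%) and MSMB (5.012%), with club cells counted also MT1G (6.982%). Reads shared between genes stay open (odds ratio 1.45, Fisher's exact p = 0.2052). The test counted pseudogene copies by name and overlaps on the same strand, at 54.9% of the set and 45.64% of the others. It did not count related genes, such as MTRNR2L10 with MTRNR2L12 or MT1E with MT1G, so it cannot decide. The 37 lower genes had short transcripts, with a median of 1815 nt against 3528 (permutation p = 1e-04, the smallest possible) and 2794 at matched levels (p = 0.0012), but the 14 higher genes were short too, at 1542 nt (permutation p = 0.0003), so length did not go with the direction; an effect of read length, which the labels do not give per library, and a zone difference stay open.

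Luminal secretory genes had a negative median log2 zone difference in every other class tested except pericyte-like cells, where it was 0.37 over 6 genes with 0 called lower. Free RNA from luminal cells may account for part of it: these genes stood at a median of 5.452% of their level over all cells, but the zone fold differed from that over all cells by 1.02 on the log2 scale, just past the bound of 1. Club cells, at 28.0% to 261.4%, and the pericyte-like cells of the transition zone of donor 3, at 99.02%, go against a small free RNA share there. Expression by the cells themselves stays open as well, with a median correlation of 0.7588 with luminal cells of the same library, between the bounds of 0.5 and 0.8. These tables cannot separate the 2.

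Club cells of the zones came from different clusters. Within cluster 4 alone the 6 of 13 called genes that could be tested kept 52.26% of their median log2 difference, and those called with the block 46.59%. The first lies between the bounds of 50 and 80 (quartiles 46.52 to 57.78) and the second, over 431 genes, under 50. Cluster 4 may itself hold more than 1 kind of cell, as 409 of its 1945 cells were named neuroendocrine at a finer clustering, so these shares do not hold the kind of cell fixed. A difference in cluster makeup may thus account for part of the pattern, and a zone difference in the same kind of cell stays open.

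For each comparison of 3 against 3 libraries there are 10 splits, too few for a share under 0.05. Without the block the real count was 0, which each of the 10 splits reaches by construction, so these counts of splits test nothing. The highest other count was 0 in basal cells, 2 in hillock cells, 264 in fibroblasts and 0 in all cells summed. The split of fibroblasts with 264 genes set the peripheral zone library of donor 1 and the transition zone libraries of donors 1 and 2 against the rest. What lay behind these calls was not tested. With the block, 4 splits part every pair, also too few. The real one alone reached its count in basal cells (1 of 4; 90, highest other 0), hillock cells (1 of 4; 232, highest other 16) and fibroblasts (1 of 4; 30, highest other 2), while in all cells summed the real count was 0, which 4 of 4 reach by construction. For lists in basal, hillock and fibroblast cells, adjusted within each class rather than over all classes, 8 of 10 splits passed as many as the real one (11; highest other 16).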

How the results depend on the processing

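With the donor as a replicate block the zone counts rose from 0 to 183 (luminal), 90 (basal), 232 (hillock), 30 (fibroblast), 331 (endothelial), 23 (cluster 14), 11 (myeloid) and 129 (pericyte-like), from 13 to 526 (club), and lists from 33 to 50. No filter on low counts gave 236 (club), 5 (hillock), 21 (fibroblast), 16 (endothelial), 3 (myeloid), 9 (pericyte-like) and 1 (luminal against basal). DESeq2 gave 11 (basal), 73 (club), 9 (hillock), 2 (fibroblast), 41 (all cells), 2 (pericyte-like) and 1 (luminal against basal). Club counts were 53 at resolution 2.0, 22 without marker genes in the clustering and 0 within 1 cluster; hillock counts were 1 with doublets kept and 2 without marker genes, and cluster 14 gave 1 with doublets kept. Lists fell to 0 with an estimated correlation, with or without the block, and by fry.

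With the block, at most 10% mitochondrial UMIs gave 80 (luminal), 54 (basal), 66 (hillock), 67 (endothelial), 26 (myeloid) and 41 (pericyte-like). Doublets kept gave 81, 204, 47, 116 and 25 in the first 5 of these, and 9 in cluster 14. Resolution 2.0 gave 110 (luminal), 201 (basal) and 17 (myeloid). Clustering without marker genes gave 41 (luminal), 330 (club), 145 (endothelial) and 28 (myeloid). Best-score names gave 244 (basal) and 79 (pericyte-like), and 1 club cluster 13. Without the genes that shift alike, 12 were left in cluster 14 and 3 in myeloid cells, as fewer genes were counted.

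Leaving out a library or donor gave 0 to 9 (luminal), 0 to 104 (club), 0 to 1 (hillock), 0 to 1 (fibroblast), 0 to 7 (endothelial), 0 to 12 (cluster 14), 0 to 10 (myeloid), 0 to 10 (pericyte-like) and 0 to 8 (luminal against basal). In classes with 2 transition zone libraries some of these fits held 1, assumed to vary like the other zone. With the block it gave 34 to 497 (basal), 92 to 128 (hillock), 35 to 197 (fibroblast), 34 (myeloid), 83 (pericyte-like) and 0 to 435 (all cells). The cause was not tested for any of these.

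In luminal cells heat shock genes reversed, from a median of -0.52 to 0.22 with the block, and androgen-regulated genes (median 0.06676, -0.13 with the block) were up by fry and down by camera. Of 722 settings for 98 genes named with the block 542 kept their call, 180 lost it and 0 reversed; for 10 genes named without it 94 of 136 kept it. The 171 settings for 19 hormone and signalling genes and the 64 for 4 shares changed no call, though the difference in hillock share of all kept cells ran from 0.64 to 2.97 and that in luminal share of all kept cells from -2.44 to -0.68, and the count of 70 stayed between 56 and 74. Of 111 settings for 37 gene lists 47 stayed on their side of the threshold, 53 lost the call, 9 gained one and 2 reversed. The block changed no call of a share and left the count over all cells at 0. Not run were smooth muscle tests (1 library per zone) and club tests with doublets kept or at most 10% mitochondrial UMIs. Small classes limit what depth can show.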

Other observations

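Pericyte-like cells, the contractile cells around small vessels, were tested after the data were seen. The apolipoprotein APOE was higher in the transition zone by 2.17 ± 0.19 (log2, SE; blocked adjusted p = 4.88e-11), at 687 ± 440 CPM (SD, n = 2) against 197 ± 101 (n = 3). Complement factor D, CFD, was higher by 2.21 ± 0.20 and the chemokine CXCL2 by 1.99 ± 0.19. CFD was also among the leading genes of fibroblast cluster 12. In the transition zone library of donor 3, 1 of 2 tested here from that zone, luminal secretory genes stood in pericyte-like cells at 99.02% of their level over all cells. The oestrogen receptor ESR1 fell by 1.54 ± 0.33 and the lipase LPL fell by 1.99 ± 0.40. With the donor as a block 129 of 7564 genes were called, 85 higher and 44 lower, from 2 donor pairs. Without it edgeR called 0 (68 at an unadjusted p under 0.05; DESeq2 called 2), 9 with no filter on low counts, 2 without the transition zone library of donor 1 or 3 and 10 without donor 1 or donor 3, each of these leave-outs with 1 transition zone library assumed to vary like the others. The blocked count was 41 with at most 10% mitochondrial UMIs, where ESR1 and LPL lost their calls, 79 with best-score names, where LPL lost its call, and 83 without donor 2.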
